A study of Homo sapiens with 48 samples.

How the data were processed

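The deposited data held 144 tables of read counts per gene, 3 sequencing lanes (L001, L002 and L005) for each of 48 libraries, and 1 table of FPKM values. Per the file headers the counts were made with featureCounts 1.5.0 from paired, reverse-stranded fragments over exons grouped by gene, on the UCSC hg38 gene models, from TopHat alignments, without multi-mapping or overlapping assignments. Per the submitters' processing notes reads were converted with bcl2fastq 1.8.4, aligned with TopHat2 2.1.0 to hg38 and counted with Subread 1.5.1, a version that differs from the file headers. Per the labels' protocols U2OS cells were edited with CRISPR-Cas9, plated overnight, treated, and their RNA was taken with DNase digestion into stranded poly(A)-selected libraries. The design text names biological quadruplicates, so n = 4 in each of 12 groups. The deposited count tables hold counts, which were summed over the 3 lanes, and the authors' normalized table holds FPKM values, whose ratio to FPKM made here from the counts was a single factor per library, from 0.9345 to 1.092, in 100% of genes within a tolerance of 1e-06. It served for 1 alternative only.

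Libraries held 15.096 M to 26.09 M counts (median 19.204 M) over 26485 genes, with 17496 to 18731 genes detected and 4.147 to 8.081% of counts in the top 10 genes. Lanes of a library differed by little more than counting noise, with a chi-square per degree of freedom of 1.034 to 1.1509 for L001 against L002 and 1.1103 to 1.267 for L001 against L005, while the 72 replicate pairs gave 7.229 to 48.658, so no library was a copy of another in its group. The tables name 0 mitochondrially encoded genes, and 1205 genes have exons on more than 1 sequence. Positions were taken from the main chromosome, and genes not on exactly 1 main chromosome were left out of windows and neighbouring genes.

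Counts were tested in R 4.3.3 with edgeR 4.0.16. All 12 groups were fitted together (glmQLFit, glmQLFTest, 36 residual degrees of freedom, common dispersion 0.01617) after filterByExpr, which left 15496 genes and removed 10989, and TMM normalization, with factors from 0.9071 to 1.082. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. Standard errors were the log2 fold change over the root of its F value. The 20 comparisons were the 3 stresses in wild type, each knockout against wild type in the 4 conditions, and the differences of the 3 responses between HSF1-KO and wild type, HSF2-KO and wild type, and HSF1-KO and HSF2-KO. Levels are CPM on TMM-scaled library sizes, as mean ± SD.

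Gene lists were drawn up without sight of the values and tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 500 tests, and repeated with an estimated correlation. The 26 lists, with tested of listed members, were classical HSF1 targets (27 of 28), the HSP70 and HSP110 family (14 of 16), the DNAJ family (32 of 32), small heat shock proteins (6 of 10), HSP90, HSP60 and co-chaperones (25 of 26), the TRiC chaperonin (8 of 8), proteasome subunits (34 of 34), ubiquitin and autophagy (21 of 21), ER chaperones and degradation (21 of 21), ATF4 and CHOP targets (22 of 22), NRF2 genes (21 of 21), metallothioneins (4 of 10), immediate-early genes (22 of 23), p53 targets (20 of 20), the BCL2 family (16 of 16), cell division (39 of 39), cytosolic ribosomal proteins (74 of 74), cholesterol synthesis (23 of 23), the cadherin superfamily (40 of 58), clustered protocadherins (45 of 53), integrins (22 of 25), extracellular matrix and osteoblast genes (23 of 30), interferon-stimulated genes (20 of 27), replication-dependent histones (17 of 25), mitochondrially encoded genes (0 of 28) and markers of other cell types (14 of 26). List counts were also adjusted over the list alone.

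Genes to be named were chosen from candidates set by a fixed rule. Among genes that passed, with a symbol that is not a locus or clone name, a mean of at least 2 CPM in a compared group and replicates that did not overlap, the 10 largest rises and 10 largest falls could be named (5 and 5 for knockouts under stress and for differences of responses), together with HSF1, HSF2 and up to 4 members of each list with the smallest p. Genes with few counts, or whose call ended when 1 library was left out, were mostly passed over.

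Each result was recomputed under other settings: DESeq2 1.42.0 size factors, library size only, the DESeq2 Wald test, limma-voom, no filter (22607 genes), only the compared groups, lane L001 or L005 alone, the replicate number as a replicate block, the authors' FPKM with limma (pseudocount 0.1), which changes the values and the test together, and each library left out in turn. Chosen after seeing the data were the removal of the 3 libraries with the highest RN7SK level, the same settings applied to the overlaps, the medians of lists under other scalings, and the test of the chromosome 6 histones without HSF1-KO control replicate 1. Overlaps with shared controls were set against independent lists, 20 simulations of unchanged groups and the 4 controls split into separate pairs. The same splits of libraries were counted for each comparison, all 35 for a pair of groups and 100 drawn for a difference of responses.

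Whether replicate numbers pair libraries across groups was checked on residuals of 8324 genes. Every same-number pair correlated above 0.1 in 6 comparisons, namely bortezomib 10 h in wild type, HSF2-KO control, HSF1-KO with bortezomib 6 h and with heat shock, and HSF2-KO with bortezomib 10 h and with heat shock. The replicate block moved none of their counts by more than 1.5 times.

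The pipeline was tested on simulated data, with 50 genes each changed 1.5-, 2-, 4- and 8-fold. For heat shock in wild type it recovered 52, 84, 98 and 98% of them with 11 false calls, for HSF2-KO control 54, 76, 98 and 98% with 6, and for the HSF1-KO difference in heat shock response 32, 70, 88 and 94% with 9, and it called 0 of 100 random lists with limma camera. Window tests used 25 neighbouring genes, 1000 shuffles and a local trend with GC (span 0.3). Tests against neighbouring genes used 1e+05 resamples. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 handled tables and figures. Sequence reads, protein and chromatin data were not analysed here.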

Results

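Bortezomib and heat shock were compared in U2OS osteosarcoma cells with and without the heat shock factors HSF1 and HSF2, the transcription factors that switch on chaperone genes when proteins unfold. Each of 12 groups held 4 libraries, described in the deposited design text as biological quadruplicates: wild type, HSF1-KO and HSF2-KO cells, each as control, after 25 nM bortezomib for 6 h or 10 h, and after 1 h at 42 °C. The first question was whether the targeted genes themselves were lower. Values in brackets after a gene name are log2 fold changes ± standard error from the edgeR quasi-likelihood test, and a gene is said to have risen or fallen, or to be higher or lower, only where it passed that test after adjustment over all 15496 tested genes. Candidates for naming came from a rule fixed before the data were examined, and the few genes named outside it are marked. The choice among the candidates was made with their values in view.

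HSF1 was low in every HSF1-KO group and HSF2 was only modestly lower in HSF2-KO cells. HSF1 stood at 182 ± 24.1 CPM (SD, n = 4) in wild type control cells and 19.9 ± 1.91 CPM in HSF1-KO control cells (-3.19 ± 0.13), with 154.8 to 207.7 CPM in the 4 wild type libraries and 17.83 to 21.63 CPM in the 4 knockout libraries. It stayed lower in the knockout after 6 h of bortezomib (-2.87 ± 0.13), after 10 h (-2.46 ± 0.12) and after heat shock (-3.31 ± 0.13). HSF2 stood at 20.8 ± 1.28 CPM in wild type control cells and 16.6 ± 2.65 CPM in HSF2-KO control cells (-0.32 ± 0.10, adjusted p = 0.00710), and the libraries did not overlap, with 19.59 to 22.39 against 13.76 to 19.01 CPM. That call was lost without HSF2-KO control replicate 4, where the log2 fold change was -0.24 with an adjusted p = 0.058, and over all alternatives its adjusted p ran from 0.0034 to 0.121. HSF2 was lower in the knockout after bortezomib for 6 h (-0.60 ± 0.10) and 10 h (-0.59 ± 0.098), where wild type cells raised HSF2 (0.88 ± 0.099), and not separated from wild type after heat shock (-0.068 ± 0.10, adjusted p = 0.605). In HSF1-KO cells HSF2 was higher in controls (0.29 ± 0.099) and after heat shock (0.55 ± 0.10), lower after 10 h of bortezomib (-0.54 ± 0.098) and not separated from wild type after 6 h (-0.018 ± 0.098, adjusted p = 0.891). The control difference did not pass without HSF1-KO control replicate 2 (log2 fold change 0.25, adjusted p = 0.0606), HSF1-KO control replicate 4 (0.22, adjusted p = 0.0827) or WT control replicate 4 (0.26, adjusted p = 0.051), nor with only the compared groups (0.29, adjusted p = 0.0548). A transcript that persists can still carry a disrupted reading frame, and protein was not measured here.

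**Figure D1:**
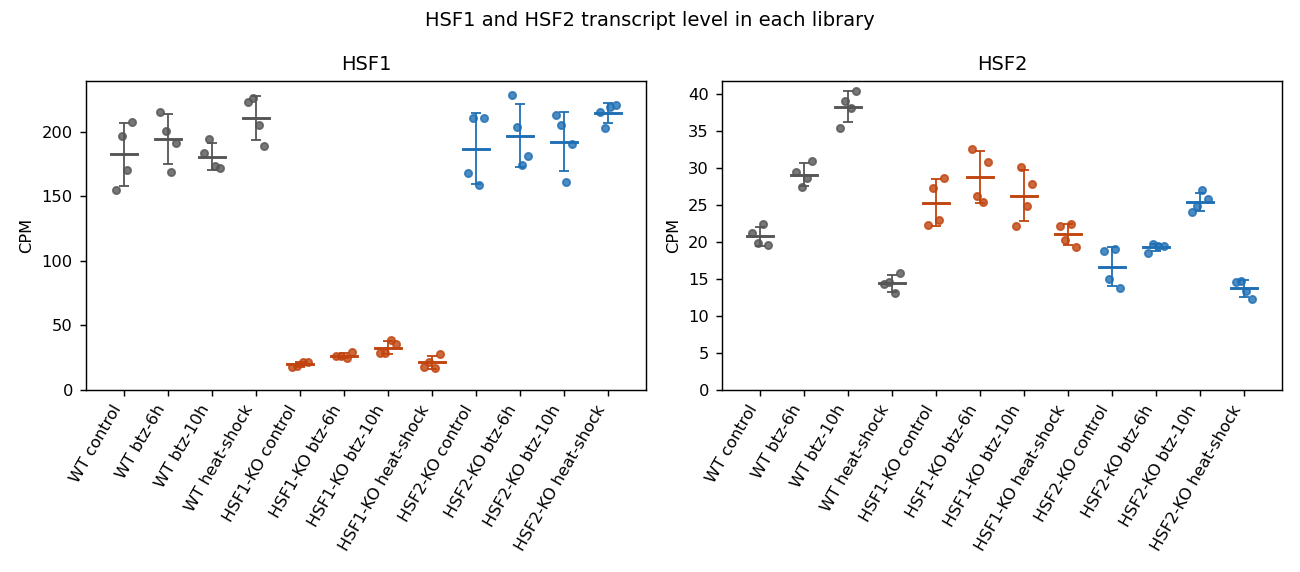
HSF1 and HSF2 in CPM in each of the 12 groups, with 1 point per library, a line at the mean and bars of 1 SD. HSF1 drops from 182 to 19.9 CPM between the wild type and HSF1-KO controls, while HSF2 moves only from 20.8 to 16.6 CPM between the wild type and HSF2-KO controls.

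Wild type cells given the proteasome inhibitor for 6 h answered with chaperones. HSPA6, an HSP70 made almost only under stress, rose (9.57 ± 0.39), as did the main inducible HSP70 genes HSPA1A (6.57 ± 0.21) and HSPA1B (6.46 ± 0.22). Reads of HSPA1A and HSPA1B, and of HSPA6 and HSPA7, are hard to tell apart, so the division within each pair is uncertain. The HSP40 co-chaperones DNAJA4 (4.94 ± 0.16) and DNAJB1 (4.20 ± 0.15), the HSP70 exchange factor BAG3 (4.32 ± 0.15) and the proteasome-binding protein ZFAND2A (4.86 ± 0.15) rose with them. Among classical HSF1 targets 27 of 27 rose and 0 fell, 27 and 0 adjusted over the list alone. Of proteasome subunit genes, 33 of 34 rose and 0 fell, 33 and 0 adjusted over the list alone, among them the base ATPases PSMC4 (1.06 ± 0.069) and PSMC2 (0.76 ± 0.054) and the lid deubiquitinase PSMD14 (0.91 ± 0.061). The cytosolic chaperonin TRiC, which folds actin and tubulin, rose as well, with 8 of 8 rose and 0 fell, 8 and 0 adjusted over the list alone and TCP1 in the lead (1.24 ± 0.057).

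Stress signalling moved in several branches at once. Of targets of ATF4 and CHOP, which answer amino acid and ER stress, 20 of 22 rose and 1 fell, 20 and 1 adjusted over the list alone, with the leucine sensor SESN2 (3.72 ± 0.17), the cystathionine lyase CTH (3.15 ± 0.17) and the mTOR inhibitor DDIT4 (4.42 ± 0.25). Of NRF2 antioxidant genes 17 of 21 rose and 0 fell, 17 and 0 adjusted over the list alone, including heme oxygenase HMOX1 (2.60 ± 0.15) and thioredoxin reductase TXNRD1 (1.12 ± 0.085). Of p53 targets 15 of 20 rose and 1 fell, 15 and 1 adjusted over the list alone, including the cell cycle inhibitor CDKN1A (1.78 ± 0.13) and the death receptor FAS (2.23 ± 0.18). The inflammatory genes CXCL8 (6.68 ± 0.56) and IL1A (4.92 ± 0.40) and the collagenase MMP1 (5.29 ± 0.41) were among the 10 largest rises. Cell division genes went down, with 1 of 39 rose and 28 fell, 1 and 30 adjusted over the list alone, as for cyclin A2 CCNA2 (-1.21 ± 0.094) and the mitotic kinase AURKA (-1.74 ± 0.15). The Hedgehog receptor PTCH1 (-3.37 ± 0.20), the Wnt receptor FZD2 (-3.24 ± 0.21), the bone regulator RUNX2 (-2.01 ± 0.23) and the antiviral IFIT1 (-3.03 ± 0.33) fell too.

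A total of 7336 genes differed, 3635 higher and 3701 lower, with 864 and 963 at least 2-fold. With library size as the only scaling 2280 were higher and 5485 lower, because the median of all genes then shifted by -0.177. The direction of small changes in this comparison therefore rests on the scaling, while each gene named here kept its sign under every scaling.

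After 10 h of bortezomib chaperone genes stood far above the controls and cell division genes below them. HSPA1A rose from 80.3 to 8155 CPM (6.67 ± 0.21), and the small heat shock protein CRYAB, which keeps unfolding proteins soluble, rose as well (3.76 ± 0.31). Of the classical HSF1 targets 27 of 27 rose and 0 fell, 27 and 0 adjusted over the list alone, and in the HSP70 and HSP110 family 14 of 14 rose and 0 fell, 14 and 0 adjusted over the list alone. Of genes for HSP90, HSP60 and their partners 17 of 25 rose and 5 fell, 17 and 5 adjusted over the list alone, with HSP90AA1 (2.53 ± 0.081). Aldo-keto reductase AKR1C1 (6.91 ± 0.36), which detoxifies carbonyls, and the interleukin 33 receptor IL1RL1 (5.83 ± 0.63) joined the 10 largest rises. The growth-linked EGR1 (-3.84 ± 0.50), the BMP antagonist NOG (-3.76 ± 0.25) and the mitotic activator CDC20 (-2.41 ± 0.17) fell, and of cell division genes 0 of 39 rose and 35 fell, 1 and 35 adjusted over the list alone. Histone HIST1H2AC fell as well (-3.48 ± 0.27), and of replication-dependent histones 0 of 17 rose and 11 fell, 0 and 11 adjusted over the list alone, and adjusted p = 0.272 with an estimated correlation.

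The remaining gene lists gave a mixed picture at 10 h. Of NRF2 genes 17 of 21 rose and 0 fell, 17 and 0 adjusted over the list alone, with HMOX1 (3.26 ± 0.16) and the growth inhibitor OSGIN1 (2.25 ± 0.15), and of ATF4 and CHOP targets 21 of 22 rose and 0 fell, 21 and 0 adjusted over the list alone, with asparagine synthetase ASNS (2.096 ± 0.11). In the ubiquitin and autophagy list 14 of 21 rose and 1 fell, 14 and 1 adjusted over the list alone, with the autophagy receptor SQSTM1 (1.74 ± 0.10), and among p53 targets 16 of 20 rose and 1 fell, 16 and 1 adjusted over the list alone. Of proteasome subunits 32 of 34 rose and 1 fell, 32 and 1 adjusted over the list alone, and adjusted p = 0.0567 with an estimated correlation. Of TRiC subunits 7 of 8 rose and 0 fell, 7 and 0 adjusted over the list alone, and adjusted p = 0.254 with an estimated correlation. Of ER chaperones and degradation genes 18 of 21 rose and 0 fell, 18 and 1 adjusted over the list alone, and adjusted p = 0.182 with an estimated correlation, with the chaperone HSPA5 (1.90 ± 0.12) and the ubiquitin-like HERPUD1 (2.23 ± 0.10). Of the DNAJ family 15 of 32 rose and 4 fell, 15 and 4 adjusted over the list alone, and adjusted p = 0.217 with an estimated correlation. Small heat shock proteins stood at 3 of 6 up and 0 down, 3 and 0 adjusted over the list alone, and BCL2 family genes at 6 of 16 up and 4 down, 7 and 4 adjusted over the list alone with the pro-death BOK (-2.42 ± 0.14) and PMAIP1 (1.46 ± 0.19) in opposite directions.

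Structural and housekeeping lists moved less clearly at 10 h. Immediate-early genes stood at 9 of 22 up and 7 down, 10 and 8 adjusted over the list alone, with ATF3 (2.55 ± 0.18) and FOSL2 (-1.85 ± 0.12) on opposite sides, and cytosolic ribosomal proteins at 6 of 74 up and 0 down, 0 and 0 adjusted over the list alone. Cholesterol synthesis genes stood at 8 of 23 up and 8 down, 9 and 8 adjusted over the list alone, with a median above 0 and a mean below it, and lanosterol synthase LSS fell (-1.93 ± 0.14). The cadherin superfamily stood at 12 of 40 up and 8 down, 12 and 8 adjusted over the list alone, clustered protocadherins at 12 of 45 up and 5 down, 11 and 3 adjusted over the list alone and integrins at 10 of 22 up and 4 down, 10 and 4 adjusted over the list alone. Extracellular matrix and osteoblast genes stood at 4 of 23 up and 2 down, 3 and 2 adjusted over the list alone, with osteopontin SPP1 higher (1.66 ± 0.18). Interferon-stimulated genes stood at 7 of 20 up and 3 down, 7 and 3 adjusted over the list alone, with STAT2 higher (1.09 ± 0.094), and metallothioneins at 0 of 4 up and 1 down, 0 and 1 adjusted over the list alone, where MT1E fell (-1.66 ± 0.13). Markers of other cell types stood at 5 of 14 up and 0 down, 5 and 0 adjusted over the list alone, led by the neuronal MAP2 (3.46 ± 0.29) and smooth muscle actin ACTA2 (2.34 ± 0.22). None of the 28 mitochondrially encoded genes was measured. The cadherin and protocadherin lists were drawn up knowing what the study had looked at, so they are not independent evidence.

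In all 9011 genes differed, 4467 higher and 4544 lower, with 1387 and 1240 at least 2-fold, 58.2% of those tested. Scaled by library size alone 3722 were higher and 5339 lower. Calls on whole lists held with an estimated correlation between genes for 8 of 25 lists at 10 h and 10 of 25 at 6 h.

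Heat shock at 42 °C for 1 h raised a narrower set of genes. HSPA6 (8.42 ± 0.38), HSPA1B (4.46 ± 0.20), HSPA1A (4.04 ± 0.19), DNAJA4 (4.19 ± 0.16) and DNAJB1 (3.87 ± 0.15) rose again, from 80.3 to 1325 CPM for HSPA1A. The GTPase RRAD (5.10 ± 0.50) and the immediate-early transcription factors FOSB (4.12 ± 0.25) and FOS (3.44 ± 0.38), which couple signals to growth, rose beside them. Within the HSF1 target list 26 of 27 rose and 0 fell, 27 and 0 adjusted over the list alone, and of small heat shock proteins 4 of 6 rose and 0 fell, 5 and 0 adjusted over the list alone, with CRYAB (2.26 ± 0.29) and HSPB1 (1.13 ± 0.22). Of HSP90, HSP60 and partner genes 11 of 25 rose and 0 fell, 13 and 0 adjusted over the list alone, and in the HSP70 and HSP110 family 9 of 14 rose and 1 fell, 9 and 1 adjusted over the list alone. Of immediate-early genes 11 of 22 rose and 2 fell, 12 and 3 adjusted over the list alone, and adjusted p = 0.250 with an estimated correlation, among them NR4A1 (1.57 ± 0.14). Few proteasome subunits moved, as 3 of 34 rose and 1 fell, 0 and 0 adjusted over the list alone, and adjusted p = 0.708 with an estimated correlation.

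Genes lowered by heat shock included small nucleolar RNAs, mitotic genes and protocadherins. SNORD79 (-2.19 ± 0.33), SNORD29 (-2.19 ± 0.27) and SNORD47 (-2.46 ± 0.38), which guide ribosomal RNA modification, were among the 10 largest falls, together with the host gene of miR-22 MIR22HG (-2.30 ± 0.14). Cell division genes such as the motor KIF11 (-0.66 ± 0.10) and the replication clamp PCNA (-0.61 ± 0.10) fell, and of that list 1 of 39 rose and 13 fell, 1 and 17 adjusted over the list alone, and adjusted p = 0.274 with an estimated correlation. Of clustered protocadherins 0 of 45 rose and 16 fell, 0 and 17 adjusted over the list alone, and adjusted p = 0.228 with an estimated correlation, with PCDHGC3 (-0.76 ± 0.14). The ER gene HERPUD1, which bortezomib raised, fell (-0.65 ± 0.10), and so did the antioxidant genes GCLC (-0.68 ± 0.085) and SRXN1 (-0.67 ± 0.085), while HMOX1 rose (1.46 ± 0.15). ATF4 and CHOP targets stood at 7 of 22 up and 3 down, 7 and 3 adjusted over the list alone, with a median below 0 and a mean above it.

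Heat shock changed 3079 genes, 1374 higher and 1705 lower, with 346 and 174 at least 2-fold. With library size as the only scaling 1108 were higher and 2131 lower. Calls on whole lists held with an estimated correlation for 4 of 25 lists, all of them chaperone lists.

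**Figure D2:**
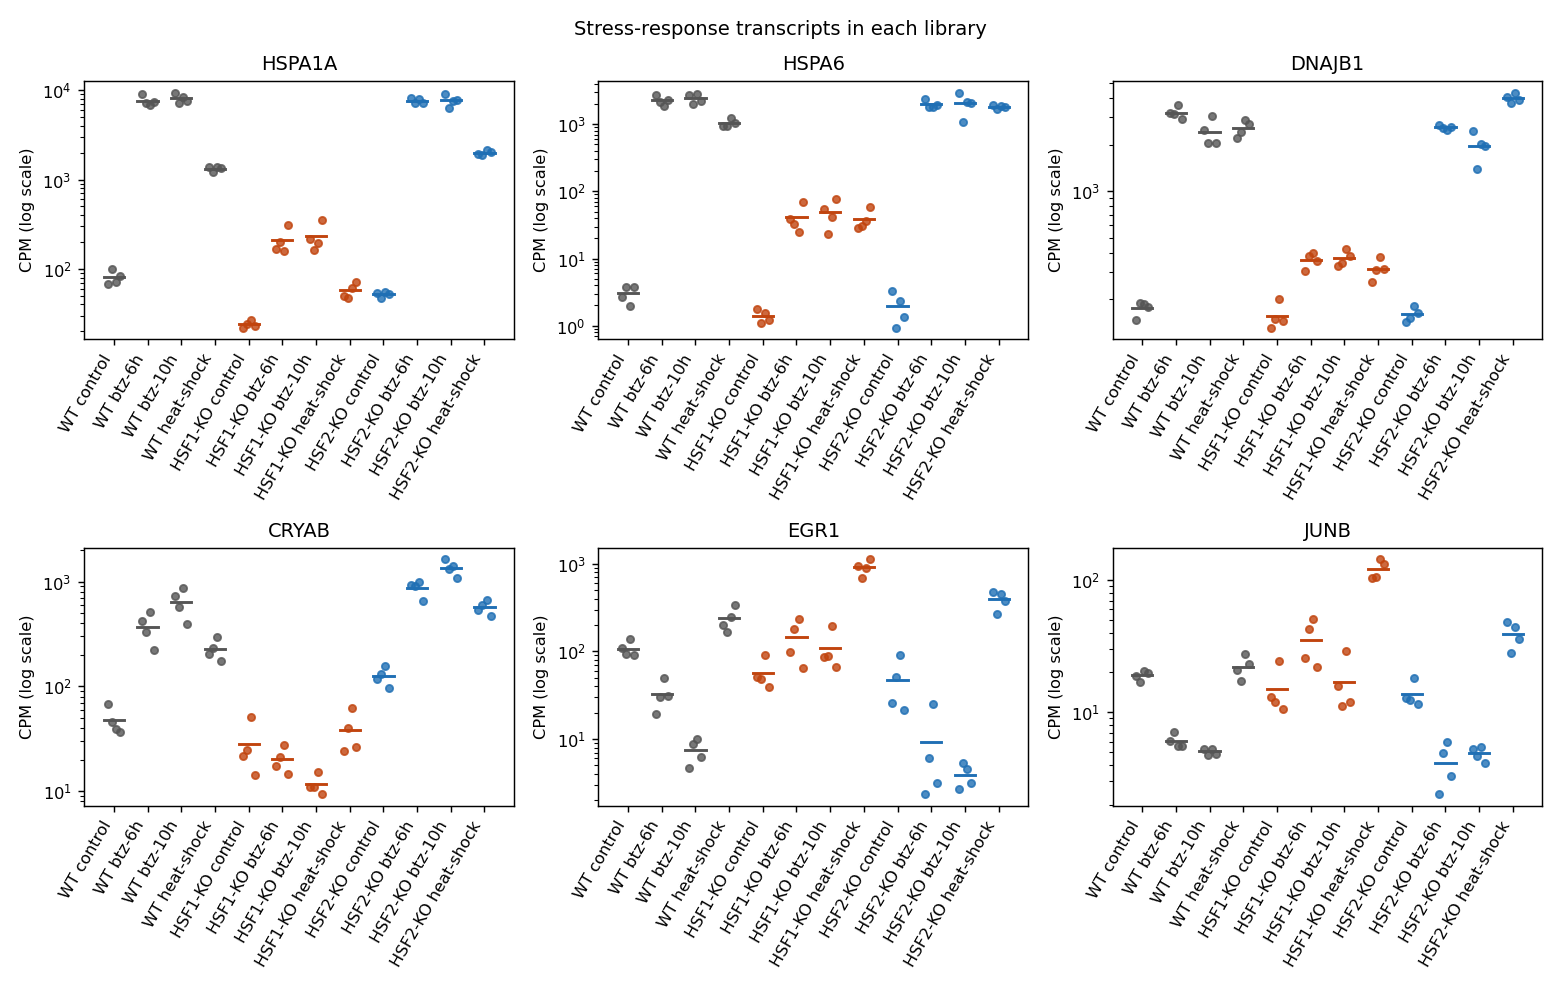
HSPA1A, HSPA6, DNAJB1, CRYAB, EGR1 and JUNB in CPM (logarithmic axis) in the 12 groups, with 1 point per library and a line at the mean. HSPA1A reaches 8155 CPM in wild type and 232 CPM in HSF1-KO cells after 10 h of bortezomib.

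Genes raised by heat shock and by 6 h of bortezomib in wild type overlapped. The 585 genes raised by both stresses, against 322.3 expected from independent lists, included HSPA1A, DNAJB1 and BAG3, and 627 were lowered by both, against 407.2. Scaled by library size alone 401 were raised and 1056 lowered by both. In the main test 559 moved in opposite directions, such as HERPUD1 and SRXN1. Both comparisons used the same 4 control libraries, which alone makes their fold changes covary. Simulated unchanged groups against shared controls gave a covariance of 0.01798 against the observed 0.1197. With the controls split into separate pairs 255 genes were raised and 274 lowered by both (median of 6 assignments), against 111.7 and 150.7 by chance. The correlation of the fold changes was 0.3062, and 0.4937 in the simulated groups, so with shared controls it carried no evidence of a common response by itself. With the controls split into separate pairs, so that no library was shared, it was 0.2522 (median of 6 assignments, lowest 0.151).

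HSF1-KO control cells lacked part of their basal chaperone supply. The HSP90 activator AHSA1 (-1.70 ± 0.072), the HSP110 chaperone HSPH1 (-1.70 ± 0.10), HSPA1A (-1.74 ± 0.18) and DNAJA1 (-1.12 ± 0.071) were lower without stress. For HSF1's own classical targets 0 of 27 were higher and 25 lower, 0 and 26 adjusted over the list alone, and of HSP90, HSP60 and partner genes 3 of 25 were higher and 16 lower, 3 and 18 adjusted over the list alone. In the HSP70 and HSP110 family 1 of 14 were higher and 9 lower, 1 and 9 adjusted over the list alone, and adjusted p = 0.0889 with an estimated correlation. Of TRiC subunits 0 of 8 were higher and 6 lower, 0 and 6 adjusted over the list alone, and adjusted p = 0.159 with an estimated correlation, with CCT4 (-0.84 ± 0.053). Of proteasome subunits 5 of 34 were higher and 17 lower, 5 and 19 adjusted over the list alone, and adjusted p = 0.546 with an estimated correlation. Of p53 targets 15 of 20 were higher and 0 lower, 15 and 0 adjusted over the list alone, led by the stress cytokine GDF15 (4.99 ± 0.45), TP53INP1 (2.60 ± 0.15) and the antiproliferative BTG2 (1.32 ± 0.11). Of ATF4 and CHOP targets 15 of 22 were higher and 2 lower, 15 and 2 adjusted over the list alone, and adjusted p = 0.155 with an estimated correlation, with the serine synthesis gene PSAT1 (1.87 ± 0.12).

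Many differences lay outside the heat shock response. Osteopontin SPP1 (-5.69 ± 0.25), the flippase ATP8B1 (-4.84 ± 0.28), the serpin SERPINB7 (-5.02 ± 0.31) and the chloride channel protein CLIC2 (-4.71 ± 0.26) were lower, and the actin linker FBLIM1 (4.76 ± 0.28), annexin ANXA10 (4.98 ± 0.23) and sciellin SCEL (4.05 ± 0.53) higher. Of extracellular matrix and osteoblast genes 3 of 23 were higher and 14 lower, 3 and 15 adjusted over the list alone, and adjusted p = 0.254 with an estimated correlation, with the fibrillar collagen COL5A2 (-2.61 ± 0.20). Of integrins 2 of 22 were higher and 11 lower, 2 and 11 adjusted over the list alone, and adjusted p = 0.233 with an estimated correlation, with ITGA4 (-2.37 ± 0.16) lower and ITGB4 (3.38 ± 0.27) higher. In the cadherin superfamily 7 of 40 were higher and 16 lower, 7 and 16 adjusted over the list alone, and adjusted p = 0.278 with an estimated correlation, with the desmosomal DSG2 (-1.25 ± 0.12). Of clustered protocadherins 0 of 45 were higher and 20 lower, 0 and 20 adjusted over the list alone, and adjusted p = 0.353 with an estimated correlation, with PCDHB6 (-2.71 ± 0.21). Of interferon-stimulated genes 2 of 20 were higher and 10 lower, 2 and 10 adjusted over the list alone, and adjusted p = 0.196 with an estimated correlation, with IFI44 (-4.01 ± 0.26). Antioxidant SRXN1 was lower (-1.47 ± 0.086), and of NRF2 genes 0 of 21 were higher and 12 lower, 0 and 12 adjusted over the list alone, and adjusted p = 0.130 with an estimated correlation.

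Histone transcripts were higher in HSF1-KO control cells. Of replication-dependent histones 17 of 17 were higher and 0 lower, 17 and 0 adjusted over the list alone, with the linker histone HIST1H1C (3.68 ± 0.22) and the core histone HIST1H2AC (3.10 ± 0.19). Histone copies share sequence, so single members are uncertain. In HSF1-KO control replicate 1 RN7SK, an RNA without a poly(A) tail chosen after its values were seen, stood at 415.3 CPM against 3.062 to 13.29 CPM in the other 3 libraries of the group, which casts doubt on its poly(A) selection or RNA. Without that library 11 histones were higher, with a median log2 fold change of 1.98 in place of 3.07. Of cytosolic ribosomal proteins 36 of 74 were higher and 1 lower, 37 and 1 adjusted over the list alone, and adjusted p = 0.708 with an estimated correlation, with RPS25 (0.92 ± 0.096) and RPL35A (-1.02 ± 0.091) on opposite sides.

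In this comparison 7128 genes differed, 3575 higher and 3553 lower, with 780 and 1004 at least 2-fold. Calls held with an estimated correlation for 4 of 25 lists, the classical HSF1 targets, the HSP90 list, p53 targets and histones. The labels name no separate lines or clones within a genotype, so a difference can belong to the line as well as to the lost gene.

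HSF2-KO control cells differed from wild type in many genes, clustered protocadherins among them. The cytokine-like matrix protein SPP1 (-7.17 ± 0.29), IFI44 (-4.92 ± 0.29) and COL5A2 (-3.69 ± 0.21) were lower, and ITGB4, the laminin-binding integrin of hemidesmosomes (4.55 ± 0.27), ANXA10 (5.66 ± 0.23), FBLIM1 (5.56 ± 0.28) and the large cadherin DCHS2 (2.47 ± 0.18) higher. Of clustered protocadherins, which give neurons and other cells surface identity, 0 of 45 were higher and 36 lower, 0 and 36 adjusted over the list alone, among them PCDHB6 (-3.96 ± 0.24) and PCDHA6 (-2.52 ± 0.23). The genes lie at hg38 chromosome 5 140786136 to 141512981. The cadherin superfamily split, with 14 of 40 up and 13 down, 14 and 13 adjusted over the list alone, as for the desmosomal DSC2 (-1.65 ± 0.17) and DSG2 (-1.28 ± 0.12). Of extracellular matrix and osteoblast genes 5 of 23 were higher and 10 lower, 5 and 10 adjusted over the list alone, and adjusted p = 0.624 with an estimated correlation, with fibrillin FBN1 (-1.33 ± 0.14) lower and the laminin LAMB1 (1.805 ± 0.14) higher.

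Several chaperone and degradation genes were lower as well. HSPB8 (-1.30 ± 0.094), its partner BAG3 (-1.25 ± 0.14) and AHSA1 (-1.04 ± 0.071) were lower, while the small heat shock protein CRYAB was higher (1.41 ± 0.29). HSPB8, BAG3 and AHSA1 lie in chromosome blocks that were lower in both knockouts, as given below. Among classical HSF1 targets 1 of 27 were higher and 18 lower, 1 and 18 adjusted over the list alone, and adjusted p = 0.226 with an estimated correlation, and of HSP90, HSP60 and partner genes 3 of 25 were higher and 12 lower, 3 and 12 adjusted over the list alone, and adjusted p = 0.412 with an estimated correlation. Of proteasome subunits 3 of 34 were higher and 24 lower, 4 and 26 adjusted over the list alone, and adjusted p = 0.267 with an estimated correlation, with PSMD11 (-0.91 ± 0.057) and PSMB1 (-0.62 ± 0.072) lower and PSMC2 (0.87 ± 0.054) higher. In the ubiquitin and autophagy list 2 of 21 were higher and 13 lower, 2 and 13 adjusted over the list alone, and adjusted p = 0.160 with an estimated correlation, with the segregase VCP (-0.77 ± 0.061) lower and the autophagy receptor OPTN (1.19 ± 0.15) higher. Of p53 targets 12 of 20 were higher and 2 lower, 15 and 2 adjusted over the list alone, and adjusted p = 0.159 with an estimated correlation, with TP53INP1 (1.92 ± 0.15) and MDM2 (0.85 ± 0.15). Of NRF2 genes 2 of 21 were higher and 9 lower, 2 and 9 adjusted over the list alone, and adjusted p = 0.335 with an estimated correlation. Histone HIST1H1C was higher (2.04 ± 0.20), and of replication-dependent histones 11 of 17 were higher and 0 lower, 11 and 0 adjusted over the list alone, and adjusted p = 0.421 with an estimated correlation. Macrophage marker CD68, a lysosomal protein also made by tumour cells, was lower (-2.69 ± 0.22).

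A total of 7460 genes differed, 3653 higher and 3807 lower, with 847 and 1090 at least 2-fold. Only the clustered protocadherins kept their list call with an estimated correlation.

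**Figure D3:**
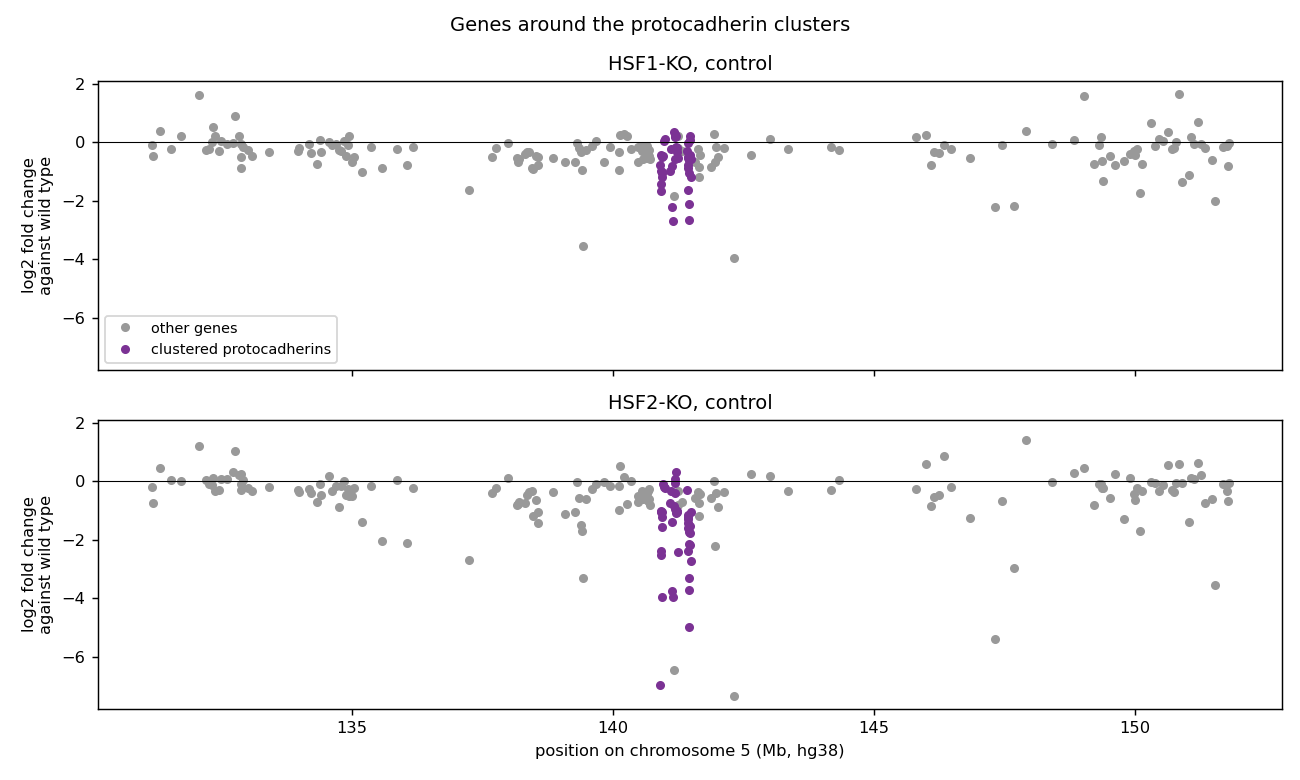
Log2 fold changes against wild type control of genes along hg38 chromosome 5 around the clustered protocadherins (position in megabases), with 1 point per gene, for HSF1-KO and HSF2-KO control cells. The clustered genes have a median of -1.29 in HSF2-KO cells, below the -0.476 of the 75 genes around them.

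The sets of genes that set the knockout lines apart from wild type controls were largely common. Both knockouts shared 2422 higher genes, against 842.8 expected from independent lists, and 2494 lower genes, against 872.9. SPP1, COL5A2, IFI44 and PCDHB6 were lower and ITGB4, ANXA10, TP53INP1 and HIST1H1C higher in both, while 115 genes differed in opposite directions. The wild type control libraries were the same in both comparisons. In simulated unchanged groups against shared controls the covariance was 0.01817 against the observed 0.5675, and with the controls split into separate pairs 1437 higher and 1550 lower genes were common (median of 6 assignments), against 394.8 and 430.3 by chance. The correlation of the fold changes was 0.7534 against 0.4973 in the simulated groups. These checks cover shared libraries only. A trait of the wild type cells themselves would appear in both comparisons with the same sign, and it was not tested.

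**Figure D4:**
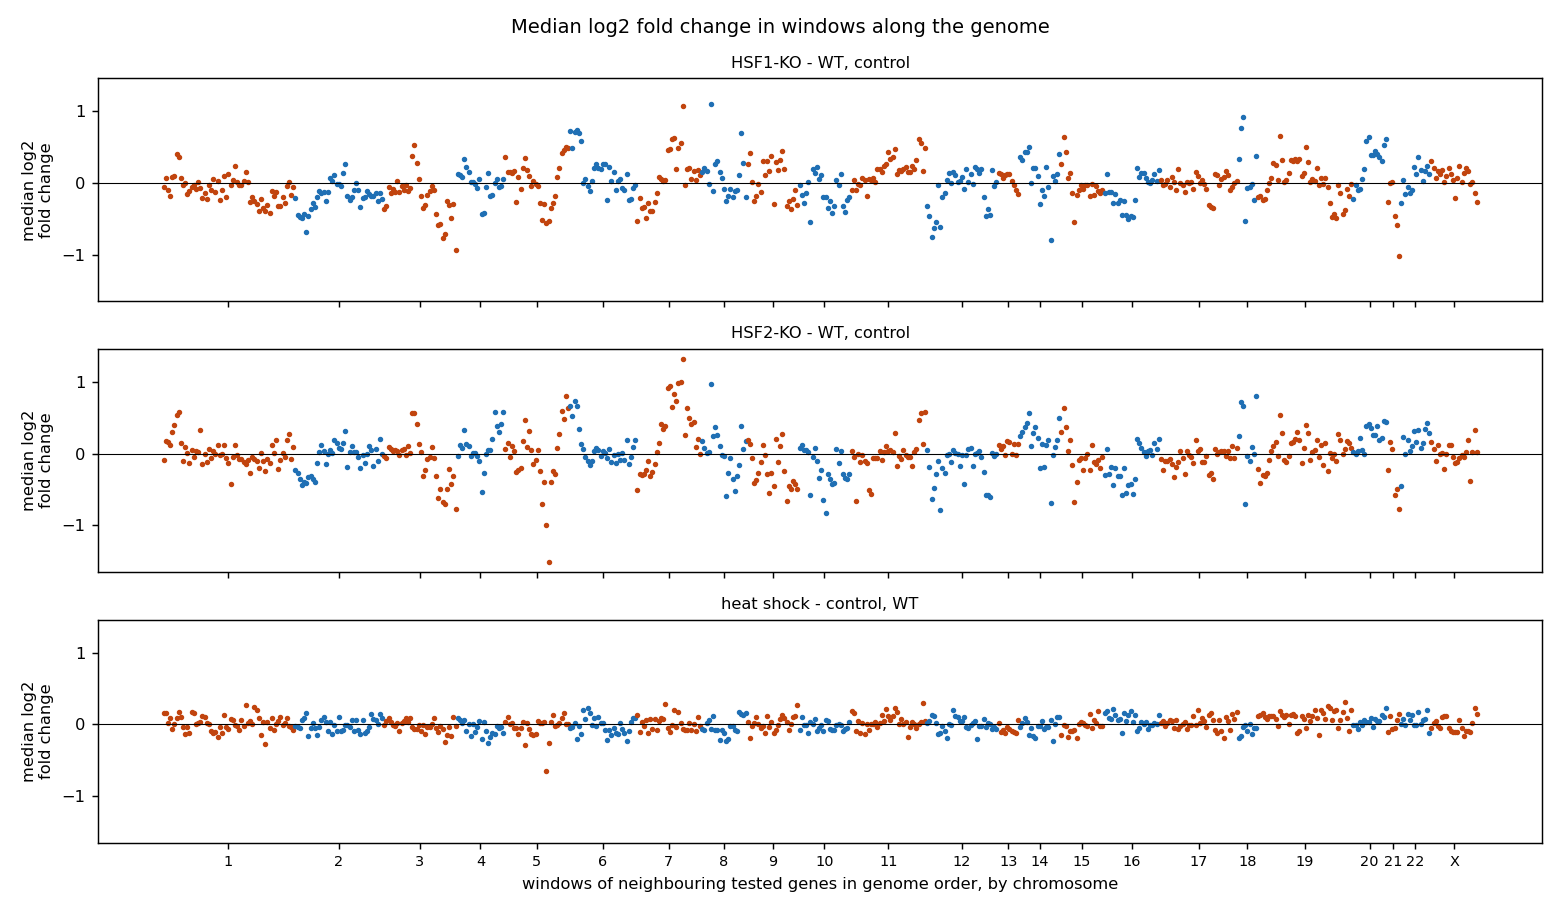
Median log2 fold change in windows of 25 neighbouring genes along the hg38 chromosomes, with 1 point per window, for HSF1-KO control, HSF2-KO control and wild type heat shock. Window medians spread more widely in the knockouts, at 2.47 and 2.56 times the spread of shuffled gene order, than after heat shock, at 1.46 times.

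After 6 h of bortezomib HSF1-KO cells fell far behind wild type cells in chaperones. HSPA6 (-5.78 ± 0.32), HSPA1A (-5.18 ± 0.20), HSPH1 (-4.11 ± 0.12), CRYAB (-4.20 ± 0.32) and HSP90AA1 (-2.64 ± 0.082) were lower than in treated wild type cells. Of the classical HSF1 targets 0 of 27 were higher and 27 lower, 0 and 27 adjusted over the list alone, and of HSP90, HSP60 and partner genes 3 of 25 were higher and 18 lower, 3 and 18 adjusted over the list alone. In the HSP70 and HSP110 family 0 of 14 were higher and 12 lower, 0 and 13 adjusted over the list alone, and of TRiC subunits 0 of 8 were higher and 8 lower, 0 and 8 adjusted over the list alone. GDF15 (5.38 ± 0.32), HIST1H2AC (4.13 ± 0.21) and the growth regulator KLF6 (2.30 ± 0.16) were higher. Of immediate-early genes 14 of 22 were higher and 0 lower, 14 and 0 adjusted over the list alone, and adjusted p = 0.197 with an estimated correlation. In all 8463 genes differed, 4460 higher and 4003 lower, with 907 and 1419 at least 2-fold. With library size as the only scaling 5270 were higher and 3344 lower, and the median of all genes stood at 0.110.

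HSF1-KO and wild type cells differed in the most genes after 10 h of bortezomib. CRYAB (-5.79 ± 0.35), HSPA1A (-5.13 ± 0.20), the mitochondrial chaperonin partner HSPE1 (-3.34 ± 0.099) and HSP90AA1 (-2.97 ± 0.083) were lower. Some proteasome genes stood the other way, with PSMD7 (1.05 ± 0.065), PSMC2 (1.19 ± 0.054) and the ubiquitin receptor ADRM1 (1.41 ± 0.11) higher, and of that list 18 of 34 were higher and 5 lower, 18 and 5 adjusted over the list alone, and adjusted p = 0.624 with an estimated correlation. Within the HSF1 target list 0 of 27 were higher and 27 lower, 0 and 27 adjusted over the list alone, of HSP90, HSP60 and partner genes 7 of 25 were higher and 17 lower, 7 and 17 adjusted over the list alone, and in the HSP70 and HSP110 family 0 of 14 were higher and 12 lower, 0 and 12 adjusted over the list alone. Of clustered protocadherins 0 of 45 were higher and 38 lower, 0 and 40 adjusted over the list alone, and adjusted p = 0.0767 with an estimated correlation. A total of 9344 genes differed, 4915 higher and 4429 lower, with 1035 and 1817 at least 2-fold. List calls held with an estimated correlation for these chaperone lists alone.

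Heated HSF1-KO cells held less chaperone and more immediate-early transcripts than heated wild type cells. HSPA1A (-4.53 ± 0.19), DNAJA4 (-4.25 ± 0.16), BAG3 (-3.37 ± 0.15) and HSPH1 (-3.19 ± 0.11) were lower than in heated wild type cells, while the mRNA decay factor ZFP36 (2.96 ± 0.15), ATF3 (2.60 ± 0.17), KLF6 (2.40 ± 0.16) and the oncogene MYC (2.06 ± 0.18) were higher. For HSF1's own classical targets 0 of 27 were higher and 27 lower, 0 and 27 adjusted over the list alone, and in the HSP70 and HSP110 family 1 of 14 were higher and 10 lower, 1 and 10 adjusted over the list alone. Of immediate-early genes 18 of 22 were higher and 1 lower, 18 and 1 adjusted over the list alone, and of p53 targets 18 of 20 were higher and 1 lower, 18 and 1 adjusted over the list alone, with the pro-death BBC3 (1.97 ± 0.16). In all 7742 genes differed, 3981 higher and 3761 lower, with 902 and 1197 at least 2-fold. Each of the list calls given here held with an estimated correlation.

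After 6 h of bortezomib chaperone genes of HSF2-KO cells lay above and below those of wild type cells. ZFAND2A (-1.76 ± 0.13), BAG3 (-0.94 ± 0.13) and HSPB8 (-0.80 ± 0.091) were lower, and CRYAB (1.23 ± 0.28) and the HSP90 partner FKBP4 (0.72 ± 0.11) higher. Among classical HSF1 targets 7 of 27 were higher and 9 lower, 7 and 9 adjusted over the list alone, with no list call. As in control cells, SPP1 (-6.45 ± 0.26), COL5A2 (-4.19 ± 0.22) and PCDHB6 (-3.63 ± 0.24) were lower and DCHS2 (2.90 ± 0.19) higher. Of clustered protocadherins 0 of 45 were higher and 31 lower, 0 and 31 adjusted over the list alone, and adjusted p = 0.0653 with an estimated correlation, and of proteasome subunits 3 of 34 were higher and 24 lower, 4 and 24 adjusted over the list alone, and adjusted p = 0.547 with an estimated correlation. CDKN1A was lower (-1.38 ± 0.12). A total of 7756 genes differed, 3895 higher and 3861 lower, with 927 and 1106 at least 2-fold.

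After 10 h of bortezomib many cell division genes were higher in HSF2-KO than in wild type cells. The replication helicase subunit MCM7 (1.12 ± 0.086), CCNA2 (0.88 ± 0.095) and the spindle factor TPX2 (0.72 ± 0.10) were higher, and of cell division genes 28 of 39 were higher and 0 lower, 29 and 0 adjusted over the list alone, and adjusted p = 0.0944 with an estimated correlation. Proteasome ATPase PSMC2 (1.36 ± 0.054) and the cholesterol enzyme CYP51A1 (1.87 ± 0.18) were higher and CDKN1A (-1.17 ± 0.12) and ZFAND2A (-1.89 ± 0.13) lower. Of the classical HSF1 targets 5 of 27 were higher and 7 lower, 5 and 7 adjusted over the list alone. Of clustered protocadherins 0 of 45 were higher and 34 lower, 0 and 36 adjusted over the list alone, with PCDHB6 (-3.59 ± 0.23), and this was the single list call that held with an estimated correlation. In all 7500 genes differed, 3775 higher and 3725 lower, with 808 and 1071 at least 2-fold.

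Chaperone genes of heated HSF2-KO cells lay on both sides of those of heated wild type cells. AHSA1 (-0.72 ± 0.070), HSPB8 (-0.53 ± 0.091) and ZFAND2A (-0.76 ± 0.13) were lower and CRYAB higher (1.32 ± 0.28), and among classical HSF1 targets 8 of 27 were higher and 8 lower, 8 and 8 adjusted over the list alone, with a median below 0 and a mean above it. SPP1 (-7.33 ± 0.29), IFI44 (-5.60 ± 0.32) and PCDHB6 (-3.42 ± 0.24) were lower, and ITGB4 (4.66 ± 0.27) and ZFP36 (1.63 ± 0.14) higher. Of clustered protocadherins 0 of 45 were higher and 33 lower, 0 and 34 adjusted over the list alone, and adjusted p = 0.0646 with an estimated correlation, and of immediate-early genes 16 of 22 were higher and 1 lower, 16 and 1 adjusted over the list alone, and adjusted p = 0.237 with an estimated correlation. A total of 7624 genes differed, 3781 higher and 3843 lower, with 905 and 1079 at least 2-fold. No list call held with an estimated correlation here or after 6 h of bortezomib.

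Responses were then compared between lines, so that a constant difference between the lines cancels, and a positive value means a response above that of the other line. A response called larger in this sense can be a smaller fall as well as a larger rise. To 6 h of bortezomib HSF1-KO cells answered with far less chaperone induction. HSPA6 (-4.67 ± 0.58), HSPA1B (-3.65 ± 0.25), HSPA1A (-3.44 ± 0.24), CRYAB (-3.46 ± 0.42), DNAJB1 (-3.01 ± 0.19) and BAG3 (-2.84 ± 0.20) had smaller responses. HSPA1A still went from 24.01 to 209.7 CPM, against 80.3 to 7604 CPM in wild type cells. Within the HSF1 target list 0 of 27 lay above and 26 below the response of the other line, 0 and 27 adjusted over the list alone, and for HSP90, HSP60 and their partners 1 of 25 lay above and 14 below the response of the other line, 2 and 14 adjusted over the list alone. For TRiC subunits 0 of 8 lay above and 6 below the response of the other line, 0 and 8 adjusted over the list alone. Growth-linked transcription factors EGR1 (3.06 ± 0.61), JUNB (2.87 ± 0.37), IER2 (1.93 ± 0.28) and MYC (1.46 ± 0.24) had larger responses, and for immediate-early genes 12 of 22 lay above and 0 below the response of the other line, 15 and 0 adjusted over the list alone.

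The responses of 1294 genes differed, 855 above and 439 below that of wild type cells, with 143 and 193 at least 2-fold. With library size as the only scaling 1330 lay above and 365 below. Calls held with an estimated correlation for the HSF1 target, HSP70, small heat shock protein, HSP90, TRiC and immediate-early lists. The number itself depended on the fit, with 757 genes when only the compared groups were fitted and 823 in lane L001. It was 1977 with the replicate block, where 16 of 24 same-number pairs correlated above 0.1.

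By 10 h of bortezomib the HSF1-KO response had parted from wild type in many more genes. CRYAB (-5.04 ± 0.43), HSP90AA1 (-2.16 ± 0.11), HSPE1 (-2.35 ± 0.13) and HSPD1, the mitochondrial chaperonin (-1.52 ± 0.11), had smaller responses. EGR1 (4.77 ± 0.65), the NRF2 partner MAFF (2.15 ± 0.28), SRXN1 (1.55 ± 0.12) and the signal adaptor TRAF1 (2.86 ± 0.64) had larger ones. For HSF1's own classical targets 0 of 27 lay above and 26 below the response of the other line, 0 and 26 adjusted over the list alone, and for HSP90, HSP60 and their partners 5 of 25 lay above and 13 below the response of the other line, 6 and 15 adjusted over the list alone. In the HSP70 and HSP110 family 2 of 14 lay above and 9 below the response of the other line, 2 and 9 adjusted over the list alone. Several proteasome genes responded more in HSF1-KO cells, as for PSMD7 (1.15 ± 0.091), ADRM1 (1.32 ± 0.16) and PSMD11 (0.87 ± 0.079), and of that list 22 of 34 lay above and 0 below the response of the other line, 27 and 0 adjusted over the list alone, and adjusted p = 0.101 with an estimated correlation. For ER chaperones, which include PDIA4 (-0.81 ± 0.17) and CALR (-0.60 ± 0.14), 0 of 21 lay above and 9 below the response of the other line, 0 and 12 adjusted over the list alone, and adjusted p = 0.400 with an estimated correlation. Antiviral signal transducer STAT2 had a smaller response (-1.73 ± 0.13), and cyclin D1 CCND1 a larger one (1.199 ± 0.17).

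A total of 4531 responses differed, 2658 above and 1873 below wild type, with 436 and 686 at least 2-fold. Calls held with an estimated correlation for the HSF1 target, HSP70 and HSP90 lists.

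In HSF1-KO cells the answer to heat shock held less chaperone and more immediate-early induction than in wild type cells. As given below, immediate-early genes as a list also responded more in HSF2-KO than in wild type cells, though less than in HSF1-KO cells. That part of the shift was therefore not particular to HSF1-KO cells. HSPA6 (-3.63 ± 0.56), HSPA1B (-3.07 ± 0.25), DNAJA4 (-3.08 ± 0.23), DNAJB1 (-2.86 ± 0.19) and ZFAND2A (-2.16 ± 0.20) had smaller responses. EGR1 (2.84 ± 0.60), JUNB (2.79 ± 0.35), the pseudokinase TRIB1 (2.96 ± 0.27), ZFP36 (2.52 ± 0.21) and MYC (2.01 ± 0.24) had larger ones. HSPA1A went from 24.01 to 57.4 CPM, against 80.3 to 1325 CPM in wild type. Among classical HSF1 targets 0 of 27 lay above and 23 below the response of the other line, 1 and 25 adjusted over the list alone, and for HSP90, HSP60 and their partners 0 of 25 lay above and 9 below the response of the other line, 0 and 11 adjusted over the list alone. For the DNAJ family 0 of 32 lay above and 5 below the response of the other line, 0 and 5 adjusted over the list alone, and in the HSP70 and HSP110 family 0 of 14 lay above and 6 below the response of the other line, 1 and 8 adjusted over the list alone. For immediate-early genes 13 of 22 lay above and 0 below the response of the other line, 17 and 0 adjusted over the list alone. In all 305 responses differed, 184 above and 121 below wild type, with 77 and 66 at least 2-fold. Lane L001 alone gave 203. These list calls held with an estimated correlation.

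Several chaperone genes had a slightly larger fold response to 6 h of bortezomib in HSF2-KO than in wild type cells. AHSA1 and most classical HSF1 targets started lower in HSF2-KO controls. After treatment those targets lay above and below wild type with no list call, so a larger response was not a higher level. HSP90 partners AHSA1 (0.54 ± 0.099), STIP1 (0.43 ± 0.084) and FKBP4 (0.77 ± 0.16), the HSP70 regulator BAG2 (0.83 ± 0.13) and HSPD1 (0.51 ± 0.11) had larger responses. Of the classical HSF1 targets 8 of 27 lay above and 1 below the response of the other line, 17 and 1 adjusted over the list alone, and for HSP90, HSP60 and their partners 7 of 25 lay above and 0 below the response of the other line, 11 and 0 adjusted over the list alone. The p53 targets CDKN1A (-0.87 ± 0.17) and BTG2 (-0.82 ± 0.15) had smaller responses, and of that list 0 of 20 lay above and 5 below the response of the other line, 0 and 9 adjusted over the list alone. Antioxidant genes SRXN1 (0.62 ± 0.12) and ME1 (0.86 ± 0.16) had larger ones. HSPA1A (0.63 ± 0.24) and HSPH1 (0.36 ± 0.14) did not pass.

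The responses of 236 genes differed, 162 above and 74 below wild type, with 44 and 25 at least 2-fold. That number moved with the libraries used, to 146 without WT control replicate 2, 149 without HSF2-KO btz-6h replicate 2, 153 without WT btz-6h replicate 3, and 156 without WT btz-6h replicate 1 or without WT control replicate 4. With limma on the authors' FPKM 152 lay above and 124 below, and 117 differed in lane L001, 130 in lane L005 and 157 with only the compared groups fitted. More differed with DESeq2 (329) and with the replicate block (555), where 18 of 24 same-number pairs correlated above 0.1. The calls on the HSF1 target, HSP90 and p53 lists held with an estimated correlation.

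After 10 h HSF2-KO cells had raised chaperone partners more, relative to their own controls, and cut cell division genes less than wild type cells. BAG2 (1.07 ± 0.13), FKBP4 (0.83 ± 0.16) and the polyubiquitin gene UBB (0.60 ± 0.12) had larger responses, as did the cell division genes CCNA2 (0.94 ± 0.13), the centromere histone CENPA (1.204 ± 0.21) and the mitotic kinase AURKB (1.03 ± 0.20). For cell division genes 20 of 39 lay above and 0 below the response of the other line, 27 and 0 adjusted over the list alone, and for HSP90, HSP60 and their partners 9 of 25 lay above and 0 below the response of the other line, 14 and 0 adjusted over the list alone. For NRF2 genes 6 of 21 lay above and 0 below the response of the other line, 8 and 0 adjusted over the list alone, with SRXN1 (1.09 ± 0.12) and thioredoxin TXN (0.43 ± 0.10). TP53INP1 (-1.06 ± 0.20) and SESN2 (-0.89 ± 0.22) had smaller responses, and for p53 targets 0 of 20 lay above and 7 below the response of the other line, 0 and 12 adjusted over the list alone. Within the HSF1 target list 9 of 27 lay above and 1 below the response of the other line, 14 and 1 adjusted over the list alone, and adjusted p = 0.0715 with an estimated correlation. For proteasome subunits 16 of 34 lay above and 0 below the response of the other line, 21 and 0 adjusted over the list alone, and adjusted p = 0.0547 with an estimated correlation, with PSMC1 (0.52 ± 0.087). A total of 824 responses differed, 495 above and 329 below wild type, with 119 and 102 at least 2-fold, and 484 in lane L001 and 546 in lane L005 alone. The replicate block gave 1480, with 21 of 24 same-number pairs correlated above 0.1. Calls held with an estimated correlation for the HSP90, NRF2, p53 and cell division lists.

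Few genes passed as answering heat shock differently in HSF2-KO and wild type cells. HSPB8, which with BAG3 routes misfolded proteins to autophagy, had a larger response in HSF2-KO cells (0.76 ± 0.13). It started from a lower control level and stayed lower than in heated wild type cells. HSPH1 (0.59 ± 0.14), BAG3 (0.65 ± 0.19) and DNAJB1 (0.78 ± 0.19) leaned towards a larger response without passing. HSPH1 (adjusted p = 0.0424) and DNAJB1 (adjusted p = 0.0425) passed with DESeq2, and DNAJB1 with only the compared groups fitted (adjusted p = 0.0298). With the replicate block HSPH1 (adjusted p = 0.00522) and DNAJB1 (adjusted p = 0.00643) passed too, though only 18 of 24 same-number pairs correlated above 0.1 here. For HSF1's own classical targets 3 of 27 lay above and 0 below the response of the other line, 15 and 0 adjusted over the list alone, and for immediate-early genes 4 of 22 lay above and 0 below the response of the other line, 11 and 0 adjusted over the list alone. These list calls held with an estimated correlation, although few members passed singly. In all 15 responses differed, 14 above and 1 below wild type, with 11 and 1 at least 2-fold, and 19 and 6 with limma on the authors' FPKM. DESeq2 gave 26, the replicate block 39, and lanes L001 and L005 alone 6 and 8. The number fell to 1 without WT heat-shock replicate 2 or without WT control replicate 4, to 5 without WT control replicate 1, and to 9 without HSF2-KO control replicate 1 or 4, without HSF2-KO heat-shock replicate 1 or without WT heat-shock replicate 4. HSPB8 was the gene that stayed.

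The knockout lines were last compared with each other, which leaves wild type cells out. To 6 h of bortezomib HSF1-KO cells answered with less HSPA6 (-5.11 ± 0.60), HSPA1A (-4.07 ± 0.25), CRYAB (-3.28 ± 0.41), HSP90AA1 (-2.30 ± 0.11) and TCP1 (-1.12 ± 0.080) than HSF2-KO cells, and with more JUNB (2.95 ± 0.38), MYC (1.77 ± 0.24) and DUSP1, a phosphatase that shuts off MAP kinases (1.54 ± 0.20). Among classical HSF1 targets 0 of 27 lay above and 27 below the response of the other line, 0 and 27 adjusted over the list alone. In the HSP70 and HSP110 family 0 of 14 lay above and 7 below the response of the other line, 0 and 7 adjusted over the list alone, and for HSP90, HSP60 and their partners 0 of 25 lay above and 14 below the response of the other line, 1 and 15 adjusted over the list alone. For immediate-early genes 13 of 22 lay above and 1 below the response of the other line, 16 and 1 adjusted over the list alone. The responses of 901 genes differed, 492 above and 409 below HSF2-KO cells, with 72 and 190 at least 2-fold. With library size as the only scaling 884 lay above and 356 below, and 456 differed with only the compared groups fitted and 581 in lane L001. The replicate block gave 1429, with 17 of 24 same-number pairs correlated above 0.1. These list calls held with an estimated correlation.

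At 10 h of bortezomib the contrast between the knockouts was wide. CRYAB (-4.71 ± 0.43), HSPA1A (-3.94 ± 0.25), HSPE1 (-2.85 ± 0.13) and STAT2 (-1.42 ± 0.13) responded less in HSF1-KO than in HSF2-KO cells, and EGR1 (4.51 ± 0.68), MYC (1.83 ± 0.24), the stress pseudokinase TRIB3 (1.91 ± 0.19) and the thioredoxin inhibitor TXNIP (3.18 ± 0.45) more. Of the classical HSF1 targets 0 of 27 lay above and 27 below the response of the other line, 0 and 27 adjusted over the list alone. For HSP90, HSP60 and their partners 4 of 25 lay above and 14 below the response of the other line, 5 and 14 adjusted over the list alone, and for small heat shock proteins 0 of 6 lay above and 5 below the response of the other line, 0 and 5 adjusted over the list alone. For immediate-early genes 12 of 22 lay above and 0 below the response of the other line, 15 and 0 adjusted over the list alone, and adjusted p = 0.165 with an estimated correlation. A total of 4080 responses differed, 2319 above and 1761 below HSF2-KO cells, with 332 and 679 at least 2-fold. The chaperone list calls held with an estimated correlation.

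Heat shock separated the knockouts in chaperones and growth-linked genes as well. HSPA6 (-5.08 ± 0.59), HSPA1A (-3.999 ± 0.25) and HSPA1B (-4.19 ± 0.26) responded less in HSF1-KO cells, and TXNIP (2.13 ± 0.44), the kinase NUAK2 (1.95 ± 0.20), the GTPase RHOB (1.90 ± 0.20) and the YAP target CYR61 (1.69 ± 0.28) more. Within the HSF1 target list 0 of 27 lay above and 24 below the response of the other line, 0 and 27 adjusted over the list alone. In the HSP70 and HSP110 family 0 of 14 lay above and 7 below the response of the other line, 0 and 7 adjusted over the list alone, and for the DNAJ family 0 of 32 lay above and 4 below the response of the other line, 0 and 4 adjusted over the list alone. For immediate-early genes 8 of 22 lay above and 0 below the response of the other line, 11 and 2 adjusted over the list alone. In all 224 responses differed, 122 above and 102 below HSF2-KO cells, with 39 and 64 at least 2-fold. These list calls, too, held with an estimated correlation.

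**Figure D5:**
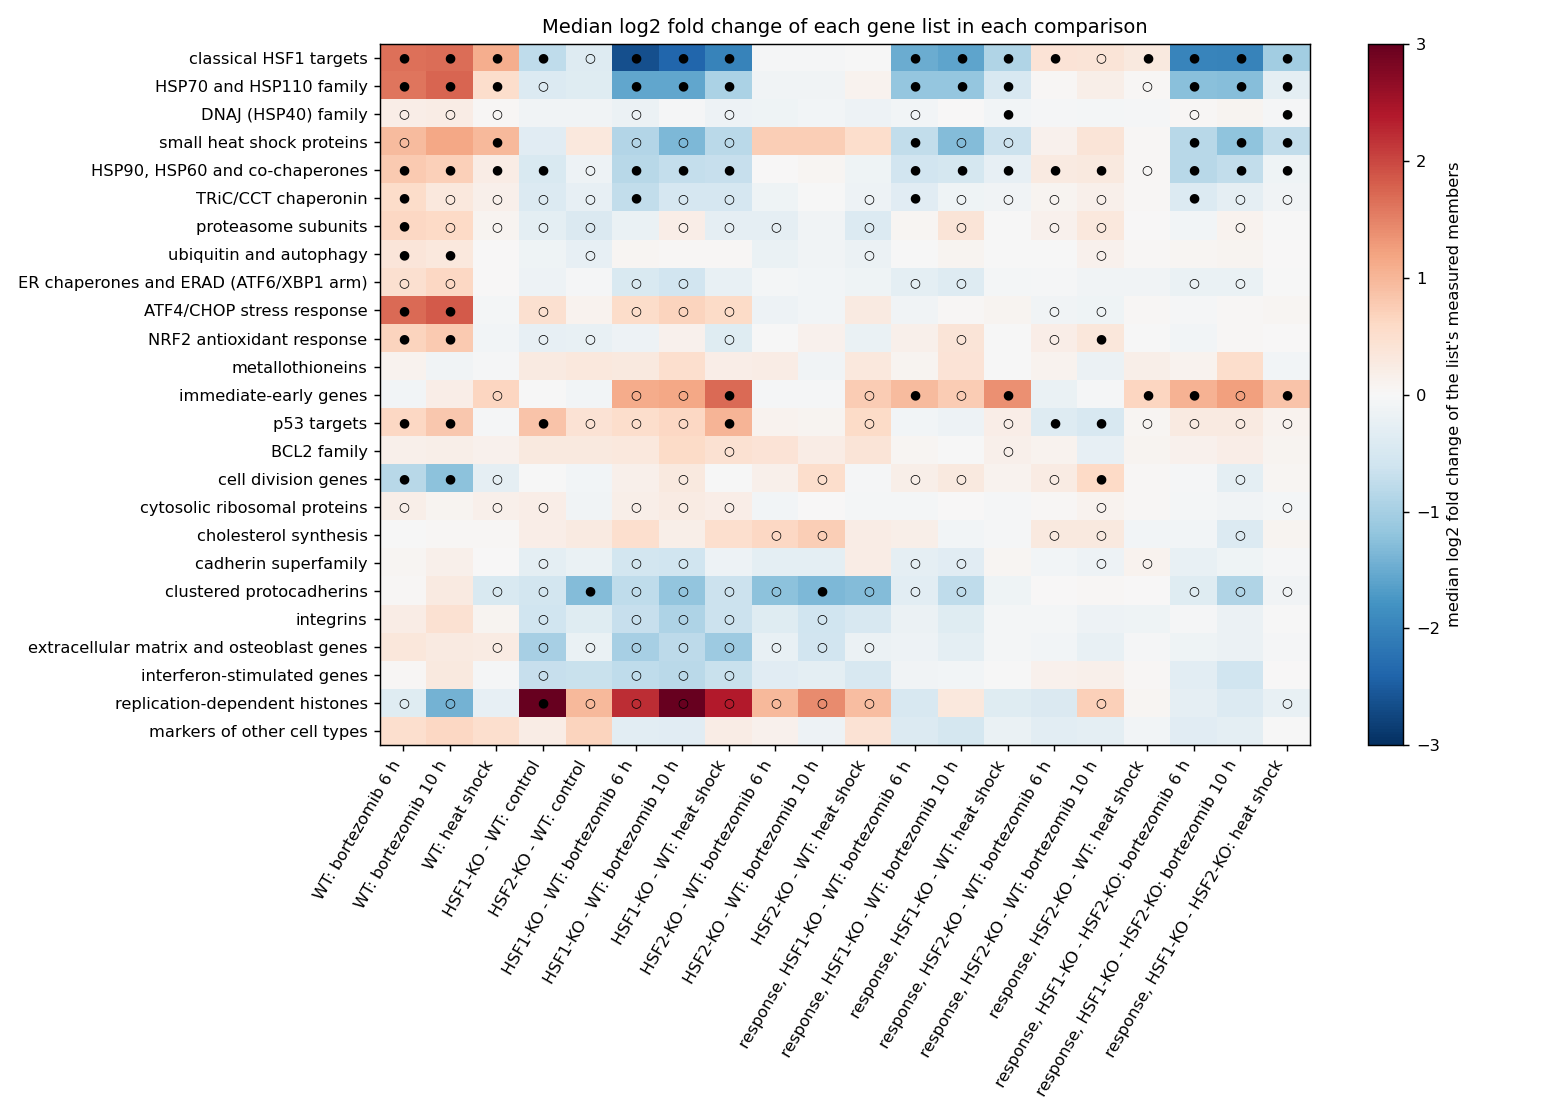
Median log2 fold change of 25 gene lists (colour, log2 units) in the 20 comparisons, with a filled circle where the list call held with an estimated correlation and an open circle where it was lost. Of 500 tests 230 were called and 79 held, among them the classical HSF1 targets, lower in every comparison of HSF1-KO with wild type cells.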

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

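Chosen only after the results were seen were the splits of the libraries and the tests given here on protocadherins, on RN7SK, RMRP and histones without HSF1-KO control replicate 1, and on chromosome windows, save the test of GC content and that of the chromosome 6 segment with all libraries.

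A library far from the other 3 of its group was found in 11 of 180 groups of 4 values by a Dixon test, and chance alone marks about 1 in 20 groups. BAG3 reached 110.3 CPM in HSF1-KO btz-6h replicate 4, against 72.66 to 77.49 in the others. HSPH1 reached 1572 CPM in HSF2-KO heat-shock replicate 3, against 1334 to 1360. EGR1 reached 195.8 CPM in HSF1-KO btz-10h replicate 3, against 65.59 to 87.5, and 25.36 CPM in HSF2-KO btz-6h replicate 3, against 2.345 to 5.993. JUNB reached 24.43 CPM in HSF1-KO control replicate 3, against 10.68 to 13. RN7SK, an RNA without a poly(A) tail, reached 415.3 CPM in HSF1-KO control replicate 1, 74.35 in WT btz-6h replicate 3, 67.53 in HSF1-KO heat-shock replicate 1, 45.81 in HSF1-KO btz-6h replicate 1 and 28.71 in WT heat-shock replicate 1. The 118.8 CPM of RN7SK in HSF1-KO btz-10h replicate 2, higher than all of these but the first, did not pass the Dixon test against 6.304 to 26.29 in the others. WT btz-10h replicate 1 held 15.096 M counts, against 17.734 M to 18.064 M in the others.

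Stress responses that differed between the lines stood out by the edgeR test of the difference itself. HSF1-KO and wild type differed in 1294 genes after 6 h and 4531 after 10 h of bortezomib and in 305 after heat shock, with chaperone genes such as HSPA1A below wild type. HSF2-KO and wild type differed in 236, 824 and 15 genes. HSF1-KO and HSF2-KO differed in 901, 4080 and 224 genes.

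Other splits of the same libraries were fitted on the compared groups alone. For 11 comparisons of a pair of groups just 1 of 35 splits, the real one, gave as many genes and the highest other gave 0. Chance placement of the libraries would put the real split first in 1 of 35 cases. The other splits mix the compared groups, which widens their spread, so their 0 calls do not measure how many calls chance gives. The real numbers were 6677, 8707 and 2480 for bortezomib 6 h, 10 h and heat shock in wild type, 6061, 7136, 8919 and 7015 for HSF1-KO as control and after each stress, and 6460, 7195, 7481 and 7650 for HSF2-KO in the same order. Of 100 drawn splits, the real one included, 3 reached the 4176 genes of the HSF1-KO difference after 10 h (highest other 4746), the 157 of HSF2-KO after 6 h (5750) and 15 after heat shock (6303), and the 3382 between the knockouts after 10 h (4598), and 4 reached the 759 of HSF2-KO after 10 h (5696). For HSF1-KO after 6 h (757, highest other 4727) and heat shock (216, highest other 5594) and between the knockouts after 6 h (456, highest other 1805) and heat shock (172, highest other 2810), 5 of 100 did. The other splits as large were all among the 6 drawn that keep the true lines in just one treatment, a description chosen after they were seen. Those hold the difference between the lines itself. Splits that mix the lines in each treatment gave at most 3 genes, but mixing widens their spread. The share of splits as large therefore cannot decide for or against chance in the differences of responses.

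Part of the differences between the knockouts and wild type lay in chromosome blocks, as the spread of window medians shows. In both knockouts 93 of 608 windows of 25 genes had medians beyond 0.3 of the same sign. They held 2325 of 15200 genes and 22.2% of the called genes of each, a share that choosing windows by these medians raises. Windows between chromosome 7 90211686 and 108574850 were among them, with medians up to 1.07 in HSF1-KO and 1.32 in HSF2-KO control cells. PSMC2, MCM7, CYP51A1 and LAMB1, named above, lie there, and their differences were not tested apart from those of their neighbours. AHSA1, HSPB8, BAG3 and ZFAND2A, named as lower in HSF2-KO groups, lie in windows that were lower in both knockout controls. The HSF2-KO medians were -0.686 on chromosome 14 (AHSA1), -0.569 on chromosome 12 (HSPB8), -0.337 on chromosome 10 (BAG3) and -0.51 on chromosome 7 (ZFAND2A). These genes were not set against their neighbours either. Over all windows the medians of HSF1-KO control spread 2.47 times as widely as in shuffled gene order, as segments of different copy number or state would give, and no shuffle of 1000 came as high, though none did for bortezomib or heat shock in wild type cells alone either, at 1.26 and 1.46 times. Removal of the trend with GC content left 2.46, which argues against GC bias as the whole cause. Windows of HSF1-KO control and of HSF2-KO after 10 h of bortezomib, which have no library in common, correlated at 0.762, and those of HSF1-KO after 10 h and HSF2-KO control at 0.691, so lines with a common history and loss of either factor cannot be told apart with a single line per genotype. The biological explanation, loss of HSF1 or HSF2, stays open.

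Clustered protocadherins were lower in HSF2-KO control cells. Their median lay -0.81 from that of the 75 genes within 5 Mb (permutation p = 1e-05, the smallest that 1e+05 resamples can give), so a lower level of the whole segment does not account for it, and the beta genes, which have no exon in common, had a median of -0.936, so reads shared within the alpha and gamma clusters are not the whole cause either. In HSF1-KO control cells the alpha genes lay -0.52 from their neighbours (permutation p = 0.00058), beyond the segment, while the beta genes lay 0.116 above them (permutation p = 0.406), the gamma genes -0.209 away (permutation p = 0.0768) and both sets pooled -0.193 away (permutation p = 0.116), so a lower segment stays open for these. After 10 h of bortezomib most clustered protocadherins were lower in HSF1-KO cells too, so lower levels were not particular to HSF2-KO cells. The stressed groups were not set against neighbouring genes. A role of HSF2, or of the line chosen, stays open as a hypothesis.

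Histone transcripts were higher in HSF1-KO control cells. Without replicate 1 11 histones were still higher, so RNA without poly(A) tails in that library is not the whole cause, though the median dropped from 3.07 to 1.98. The 15 histones at hg38 chromosome 6 26020490 to 27810536 lay 2.85 above the 54 genes within 2 Mb (permutation p = 1e-05), and 1.73 above them without replicate 1 (permutation p = 1e-05). Windows of chromosome 6 from 292057 to 27023974, which hold part of these histones, were themselves raised, with medians of 0.488 to 0.736 in HSF1-KO control. A higher level of the segment is therefore not the whole cause, but it can be part of it. RN7SK and RMRP did not pass without replicate 1, with an adjusted p = 0.451 for RN7SK and log2 fold changes of 0.881 and 0.236, so their rise belongs to that library. Loss of HSF1 and a difference of the line stay open for the histones.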

How the results depend on the processing

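The removal of the 3 libraries of highest RN7SK level (HSF1-KO control replicate 1, HSF1-KO btz-10h replicate 2 and WT btz-6h replicate 3), the settings of the overlaps and the medians of lists under other scalings were chosen after seeing the data. Of 20 counts of genes 14 stayed within 1.5 times under every setting and every library left out, and the other 6 were differences of responses. All 20 were higher with the replicate block. Over all groups 44 of 48 libraries lay closest to a library of their own number, and 211 of 264 same-number pairs correlated above 0.1 (median 0.338, lowest -0.332, against -0.107 for other numbers), a hint of pairing from the data and not the design. List medians changed sign with another scaling in 0 of 230 called lists with limma camera, and overlaps stayed within 1.5 times with both directions added up. Genes lowered by both heat shock and bortezomib moved from 627 to 1056 with library size only and 411 with lane L001. With 4 libraries per group at the depths used, 32% of simulated 1.5-fold differences of responses were recovered, so many small effects were not detectable. Single lanes hold fewer counts, and all 20 were lower in them. Single comparisons and left-out libraries leave fewer libraries, which mostly but not always lowered the counts. For the other changes named next the cause was not tested.

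The HSF1-KO difference after 6 h of bortezomib gave 1977 genes with the replicate block, 757 with only the compared groups and 823 with lane L001, and that after heat shock 203 with lane L001. The HSF2-KO difference after 6 h gave 555 with the replicate block, 157 with only the compared groups, 117 with lane L001, 130 with lane L005 and 156 without the libraries of high RN7SK, and 146 (without WT control replicate 2) to 238 with 1 library left out. It was 149 without HSF2-KO btz-6h replicate 2, 153 without WT btz-6h replicate 3 and 156 without WT btz-6h replicate 1 or WT control replicate 4. After 10 h it gave 1480 with the replicate block, 484 with lane L001 and 546 with lane L005. After heat shock it gave 39 with the replicate block, 26 with DESeq2, 6 with lane L001, 8 with lane L005 and 25 with limma on the authors' FPKM, and 1 to 14 with 1 library left out. It was 1 without WT heat-shock replicate 2 or WT control replicate 4, 5 without WT control replicate 1, and 9 without HSF2-KO control replicate 1 or 4, HSF2-KO heat-shock replicate 1 or WT heat-shock replicate 4. Between the knockouts after 6 h there were 1429 with the replicate block, 456 with only the compared groups and 581 with lane L001. The HSF2 transcript level in HSF2-KO control cells stayed lower but did not pass with only the compared groups (log2 fold change -0.32, adjusted p = 0.0566) or lane L005 (-0.24, adjusted p = 0.121), and ran from -0.38 to -0.24 with 1 library left out, where it did not pass without HSF2-KO control replicate 4 (-0.24, adjusted p = 0.058). Gene list tests gave 79 calls with an estimated correlation in place of 230.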

Other observations

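The test described next was chosen after the values were seen. Small nucleolar RNAs, which guide the modification of ribosomal RNA and mostly come from introns, fell with heat shock in each line. Of 112 measured, 68 fell and 7 rose in wild type cells (median log2 fold change -1.48, against 0.0114 for other genes), 53 fell and 6 rose in HSF1-KO cells (median -1.26), and 53 fell and 10 rose in HSF2-KO cells (median -1.23). The ribosomal RNA precursor gene RNA45S5 rose at the same time, with log2 fold changes of 4.08 ± 0.82, 2.09 ± 0.76 and 4.62 ± 0.88. In wild type cells 12 of the 112 rose and 5 fell after 6 h of bortezomib, and 16 rose and 3 fell after 10 h, when RNA45S5 rose as well (1.87 ± 0.795, adjusted p = 0.0412). RN7SK, another RNA without a poly(A) tail, stood at 12.57 to 19.66 CPM in heated and 3.031 to 4.901 CPM in control HSF2-KO cells, but heated and control libraries overlapped in wild type (4.552 to 28.71 and 1.885 to 9.343 CPM) and HSF1-KO cells (13.76 to 67.53 and 3.062 to 415.3 CPM). The drop with heat shock differed from wild type in 4 of the 112 in HSF1-KO and 1 in HSF2-KO cells, or 25 and 22 at an unadjusted p under 0.05. Libraries were selected for poly(A), so these values cover a small part of both kinds of RNA.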
